A study of Drosophila melanogaster with 2 samples.

How the data were processed

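Per the labels, chromatin immunoprecipitation with sequencing was carried out on whole embryos of a transgenic line with GFP-tagged CG1603. Chromatin was sheared by sonication to 200 to 800 bp. The antibody field of the labels names CG1603, while the description names an antibody against GFP, which was taken here as the antibody used. The 2 samples form 1 group, and the labels number them as biological replicates 2 and 3. The aligner, the peak caller and their versions are not given in the sources used here. Per the deposited description files, each peak list was derived from the immunoprecipitated reads and a control, and the reproducible list from both replicates' lists and the pooled list. Coordinates are on dm6 per the labels.

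The authors called peaks on each replicate and on the pooled replicates, and deposited each of these lists with exactly 30000 lines, so the lists were capped. Each deposited peak carries a signal value, whose scale is not stated, and the −log10 of a q value, whose highest value was shared by 71.4% of reproducible peaks and which was therefore not used for ranking. Signal was used to rank peaks within a list and, in a single test of the closing part, as a log2 ratio between the replicates with its median removed. All 8963 peaks of the reproducible list were lines of the pooled list, and they were its 8963 strongest by signal. Membership thus does not require a peak in each replicate: 8820 had one in replicate 2 and 8894 in replicate 3. Read counts are not part of peak lists, so depth is unknown, and no interval for single peaks is given.

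Genes and transcripts were taken from Ensembl release 115 (BDGP 6.54) and sequence from the RefSeq release 6 assembly, both on dm6 coordinates, and all peaks lay within its chromosome arms. A gene was called bound if a reproducible summit lay within 500 bp of any TSS of its protein-coding transcripts. Pseudogenes and transposable elements were left out. Annotation classes were given in the order promoter, 5' untranslated region, coding sequence, 3' untranslated region, intron, non-coding exon and intergenic. Random placements (1000, or 100 for the count of bound genes) kept the chromosome arm and left out unknown bases. Repeats were taken from the lower-case bases of the reference, and unknown bases were counted as masked too. Chromosomes 4 and Y were counted as repeat-rich whatever their masking.

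Tests between shares were Fisher's exact tests, two-sided unless stated, with conditional odds ratios and 95% exact intervals. Benjamini-Hochberg adjustment was made over 24 gene lists, 18 fixed motifs and all 8-mers. The lists, motifs, tests and 63 alternatives were fixed before the data were examined, and 11 alternatives were added after that. Alternatives changed the promoter distance, the peak list, the replicates used, the assignment of peaks to genes, the backgrounds and the windows. Members of lists without a match in the annotation (Endog, Ald, Dl, Z4 and n-syb) were left out or were already present under another name. Genes named in the text were those nearest to the 15 strongest reproducible peaks, up to 4 bound members of each list by signal and up to 2 unbound members in alphabetical order, 11 fixed genes, and the 3 strongest per replicate bound without any overlapping peak in the other. Peaks and genes are not independent replicates, and p values describe these 2 libraries.

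Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. The statistics were tested on simulated peaks over the real genome. For 8963 simulated reproducible peaks and 13945 genes, a planted promoter share of 46.9% was recovered as 47.1%, and a planted replicate overlap of 50.0% as 52.4% including chance. The 8-mer test was run on separate random windows against other random windows. There a planted 8-mer ranked first, with 0 8-mers called where none was planted. It was planted in a larger share of windows than TATCGATA held at summits. Summits against their own flanks were not simulated, so false calls in that comparison were not measured.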

Results

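Binding of CG1603, a zinc-finger protein known as a regulator of nuclear genes with mitochondrial functions, was mapped in whole *Drosophila melanogaster* embryos of both sexes collected 0 to 16 h after egg laying. The embryos came from a transgenic line carrying CG1603 with a C-terminal GFP tag. The antibody was taken to be against GFP, although the antibody field of the labels names CG1603. The series held 1 group with 2 biological replicates, numbered 2 and 3 in the labels. The authors' peak lists held 30000 peaks for replicate 2, 30000 for replicate 3 and 30000 for the replicates pooled. A reproducible list of 8963 peaks covered 2231 kb. No peak list of a control was analysed here, and read depth is unknown from peak lists, so that replicates were compared with each other and peaks with the rest of the genome. Peak signal is the authors' own value and was used to rank peaks within a list.

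The first comparison asked how far the replicates found the same sites. Of the 8963 strongest peaks of replicate 2, 83.1% overlapped one of the 8963 strongest peaks of replicate 3, and 83.4% of the latter overlapped one of the former. Random placement on the same chromosomes gave 3.31% (permutation of positions, p = 0.001, one-sided, the smallest that 1000 placements can give). The strongest site was the same in both replicates, the promoter of RpL23A, which encodes a protein of the large cytosolic ribosomal subunit. Any peak of the other replicate was overlapped by 99.9% of the strongest 1000 peaks of replicate 2 and by 41.2% of its peaks ranked 20001 to 30000. Across the 8751 reproducible peaks with a peak in both replicates (97.6% of the list), Spearman's rho of the signals was 0.874 (bootstrap 95% interval 0.867 to 0.879). This is a correlation across peaks, which are not independent replicates.

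Some promoter peaks among the strongest 8963 of a replicate had no partner of any rank in the other replicate. At RpL11, which encodes another large-subunit ribosomal protein, replicate 3 had a peak of rank 383 at chromosome 2R, positions 19442050 to 19442434, and replicate 2 had none. Dis3, an exosome ribonuclease gene, and trbd had replicate 3 peaks of rank 510 and 610 without a replicate 2 peak. In the opposite direction CG43116, Helz and TER94, whose product is an AAA ATPase, had replicate 2 peaks of rank 475, 1031 and 1228 without an overlapping replicate 3 peak. Helz was nevertheless bound in replicate 3 as well, through another promoter peak of rank 3882. CG43116 also had another promoter peak in replicate 3, of rank 10506 and so below the strongest 8963. Such peaks at the promoters of protein-coding genes numbered 343 for replicate 3 and 107 for replicate 2 among their strongest 8963.

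The next comparison asked where in the genome the tagged protein was found. Of the reproducible peak summits, 49.4% lay within 500 bp of an annotated transcription start site (TSS), compared with 13.4% ± 0.364 (SD over 1000 random placements within the chromosome arm), a 3.68-fold difference (permutation of positions, p = 0.001, one-sided, the smallest possible). The share was 47.5% with replicate 2 alone and 52.7% with replicate 3 alone. Introns of protein-coding genes held 31.2% of summits (random 38.8%), intergenic sequence 16.9% (random 28.2%), coding sequence 0.413% (random 13.8%) and 3' untranslated regions 0.904% (random 4.45%), each lower than in every placement. The promoter share was 60.7% among the 2240 strongest peaks and 34.8% among the 2240 weakest (odds ratio 2.89, 95% interval 2.55 to 3.27, two-sided Fisher's exact test, p = 1.02e-67).

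**Figure D1:**
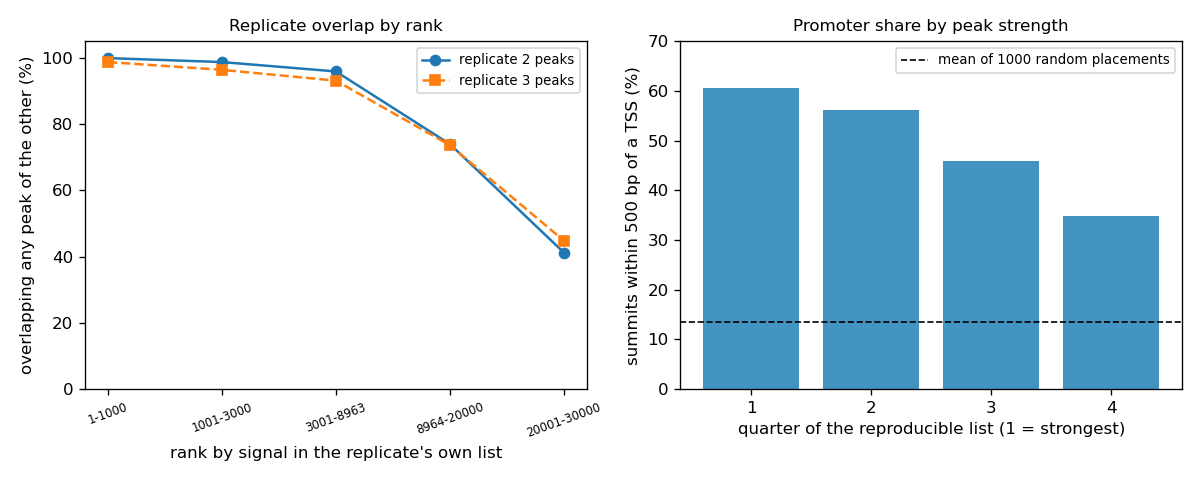
Left, percent of peaks overlapping any peak of the other replicate (vertical axis) by rank in the replicate's own list (horizontal axis), for replicate 2 (circles) and replicate 3 (squares). Right, percent of reproducible peak summits within 500 bp of a TSS (bars) by rank in 4 equal parts of the list, falling from 60.7% to 34.8%, with the mean of random placements at 13.4% (dashed line).

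All 15 of the strongest reproducible peaks were at promoters. The 3 strongest were at RpL23A (signal 35927, chromosome 3L, positions 1668405 to 1669093), eEF5, a translation factor gene (signal 27077, chromosome 2R, 24057358 to 24058259), and CG9643 (signal 25972, chromosome 2L, 2978850 to 2979464). They ranked 1, 2 and 3 in replicate 2 and 1, 3 and 2 in replicate 3. The ribosomal protein genes RpL10 and RpL15 followed at rank 5 and 13, the nuclear receptor gene Hr39 at rank 4, and tsr, which encodes cofilin, at rank 14. The others were CG1677, CG17683, CG17486, l(3)80Fj, CG5056, CG17883, vlc and MFS17. These 15 peaks lay on 2L, 2R, 3L and X, and 7 of them were in 100 kb bins with at least 30% masked repeats. Such bins, together with chromosomes 4 and Y, held 4.70% of the other reproducible peaks.

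The gene comparison asked whether mitochondrial genes were bound more often than others. Of 13945 protein-coding genes, 4919 (35.3%) had a reproducible summit within 500 bp of a TSS, compared with 7.97% under random placement, and 4457 genes were bound both with the peaks of replicate 2 (4798 genes) and with those of replicate 3 (5226 genes). Nuclear genes of the fixed mitochondrial lists were bound more often: 141 of 225 (62.7%) against 34.8% of other genes (odds ratio 3.14, 95% interval 2.38 to 4.18, two-sided Fisher's exact test, p = 4.84e-17). The odds ratio was 3.14 with replicate 3 alone and 3.27 with replicate 2 alone. It was 2.11 when each peak was given only to the gene of the nearest TSS.

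Within the respiratory chain, 27 of 40 genes for complex I, the NADH dehydrogenase, were bound (odds ratio 3.83, adjusted exact p = 0.000159). The strongest were ND-30, ND-AGGG, ND-ASHI and ND-MWFE, with peaks of rank 119, 217, 381 and 489. Their summits lay 444, 67, 255 and 179 bp from a TSS of the gene. ND-18 and ND-20L were among those not bound. All 4 complex II genes were bound (SdhA, SdhB, SdhC and SdhD, adjusted exact p = 0.0287), as were 9 of 13 complex III genes (adjusted exact p = 0.0287), led by UQCR-11 at rank 113, while Cyt-c1 was not. Complex IV with 9 of 17 genes, among them COX6B and COX5A, and ATP synthase with 9 of 17, among them sun and ATPsynC, did not pass (adjusted exact p = 0.162 for each). TCA cycle enzymes were bound in 11 of 12 cases, including Fum1, Idh3a, Idh3b and Idh3g and excepting mAcon1 (odds ratio 20.2, 95% interval 2.94 to 871, adjusted exact p = 0.000255), with an odds ratio of 9.55 without replicate 3 (10 of 12). All adjusted exact p values of gene lists are from two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 24 lists. Fum1 and ND-ASHI share a single peak, and the COX6B peak had no replicate 2 partner.

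Genes of mitochondrial gene expression and protein import follow. Of 75 mitochondrial ribosomal protein genes, 49 were bound (odds ratio 3.48, adjusted exact p = 6.98e-07), with mRpS23, mRpS30, mRpS10 and mRpL23 at rank 54, 67, 90 and 174. Their summits lay 382, 11, 136 and 117 bp from a TSS of the gene. The call for this list was lost with the gene of the nearest TSS only (odds ratio 1.30, adjusted exact p = 0.344). In mtDNA maintenance and expression 9 of 13 genes were bound (odds ratio 4.13, adjusted exact p = 0.0287, and odds ratio 6.37 without replicate 3). They included TFAM, which packages mtDNA (rank 4552), mtSSB, the mitochondrial single-stranded DNA binding protein (rank 1696, summit 387 bp from a TSS), PolG2, bsf and mTTF. PolG1, the catalytic subunit of the mtDNA polymerase, and Lon were not bound. Among the 4481 strongest peaks the mtDNA call was lost (4 of 13, odds ratio 1.49, adjusted exact p = 0.586), as were those of complex II (adjusted exact p = 0.0745), glycolytic (0.134) and neuronal genes (0.269). Mitochondrial aminoacyl-tRNA synthetases with 4 of 15 genes (LeuRS-m, ArgRS-m, SerRS-m and TyrRS-m, adjusted exact p = 0.596) and protein import with 10 of 19 (adjusted exact p = 0.169) did not pass, although Tim17b and Tim23 had peaks of rank 17 and 37.

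Cytosolic ribosomal protein genes were bound in 83 of 93 cases (89.2%, odds ratio 15.5, adjusted exact p = 2.48e-26), with odds ratios of 24.6 without replicate 2 and 11.9 without replicate 3. Glycolytic enzymes were bound in 9 of 13 cases (adjusted exact p = 0.0287), among them Gapdh2, Pglym78, Ldh and Pgk, a call lost without replicate 3 (adjusted exact p = 0.0989). Genes of the Dom/Tip60 chromatin remodelling complex were bound in 13 of 15 cases (adjusted exact p = 0.000212), with Nipped-A at rank 44, and YL-1 at rank 5553, and with DMAP1 and Ing3 unbound. The odds ratio was 11.9, and 7.64 without replicate 3, and the call was lost among the 4481 strongest peaks (odds ratio 2.93, adjusted exact p = 0.0919). Insulator and promoter-binding protein genes were bound in 11 of 15 cases (odds ratio 5.05, adjusted exact p = 0.0120, and odds ratio 7.64 without replicate 3), led by Chro, Clamp, Cp190 and Trl. Dref, M1BP and BEAF-32 were bound as well, at rank 913, 4195 and 5340. Proteasome subunits with 24 of 48 genes (adjusted exact p = 0.0675), cytosolic aminoacyl-tRNA synthetases with 10 of 18 (adjusted exact p = 0.113), signalling genes with 10 of 22 (adjusted exact p = 0.406) and muscle genes with 4 of 17 (adjusted exact p = 0.467) did not pass. Regulators of mitochondrial genes were bound in 7 of 10 cases (adjusted exact p = 0.0601), including cnc, Ets97D, ewg, Adf1, srl (a PGC-1 homolog) and CG1603 itself.

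Several further lists were bound less often than other genes. Chemosensory receptor genes were bound in 4 of 179 cases (odds ratio 0.0412, adjusted exact p = 1.59e-26), cuticle protein genes in 3 of 117 (odds ratio 0.0477, adjusted exact p = 2.28e-17, with 1 bound without replicate 2 and 2 without replicate 3, odds ratios 0.0142 and 0.0328) and patterning and Hox genes in 4 of 33 (tin, bcd, vnd and cad, odds ratio 0.253, adjusted exact p = 0.0127, and 0.0806 with the gene of the nearest TSS only). Among neuronal genes 1 of 14 was bound, elav, which encodes an RNA-binding protein (adjusted exact p = 0.0415), a call lost without replicate 3 (adjusted exact p = 0.0665). None of 111 replication-dependent histone genes was bound (Wilson 95% upper limit 3.35%, adjusted exact p = 8.93e-21), which are near-identical repeated copies to which reads may not be assigned uniquely.

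**Figure D2:**
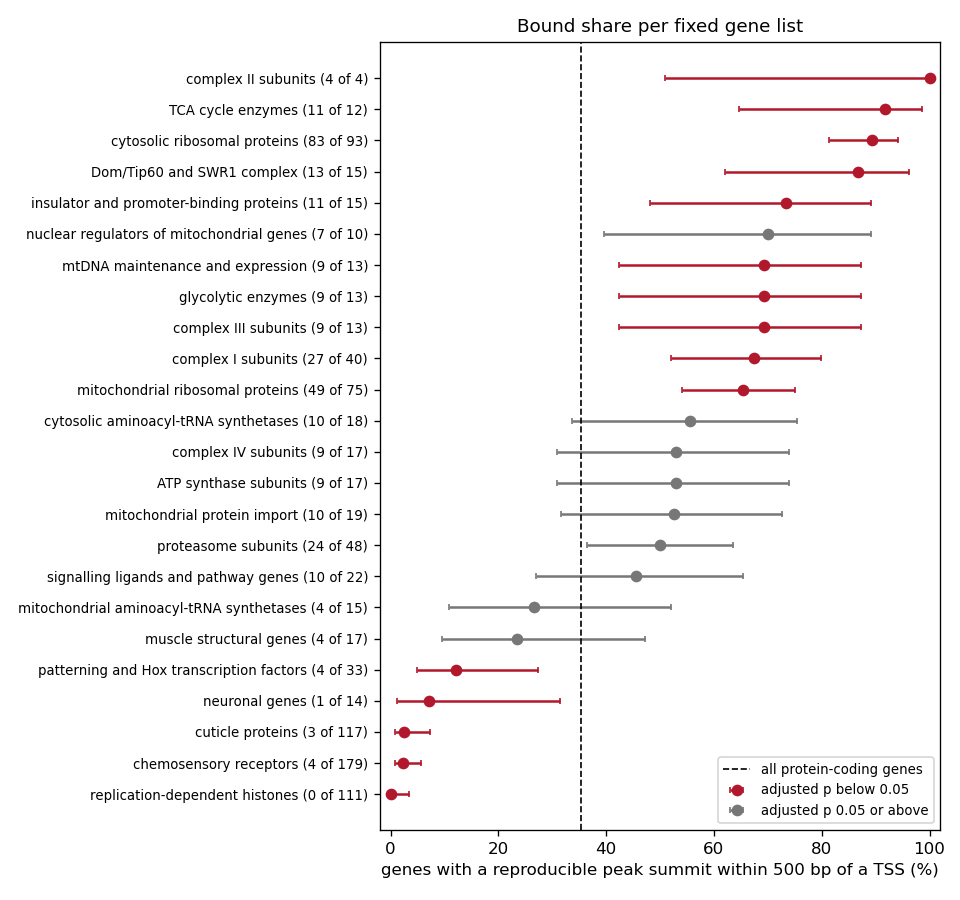
Percent of genes in each of 24 fixed lists with a reproducible peak summit within 500 bp of a TSS (horizontal axis), with Wilson 95% intervals as bars and counts in the labels. Red points passed an adjusted p of 0.05, and the dashed line marks the 35.3% of all protein-coding genes; cytosolic ribosomal protein genes stood at 89.2% and chemosensory receptor genes at 2.23%.

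The X chromosome and the autosomes did not differ detectably. On X, 36.1% of 2196 genes were bound, against 34.9% of 11669 genes on 2L, 2R, 3L and 3R (odds ratio 1.06, 95% interval 0.958 to 1.16, two-sided Fisher's exact test, p = 0.273). Genes with a head-to-head neighbour within 500 bp were bound in 59.6% of 3815 cases against 26.1% of others (odds ratio 4.16, 95% interval 3.85 to 4.51, Fisher's exact test). One peak can mark both genes of such a pair, and the odds ratio was 1.54 when each peak counted for the gene of the nearest TSS only.

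Sequence at the summits was compared with sequence 500 bp to either side. The DNA replication-related element (DRE), TATCGATA, was in 4.61% of windows of 50 bp to either side of summits and 0.379% of flank windows (odds ratio 12.7, 95% interval 9.78 to 16.7, adjusted exact p = 5.37e-127). Motif 1, GGTCACACT, the site of M1BP, was in 2.54% and 0.234% (odds ratio 11.1, adjusted exact p = 2.82e-67), and the BEAF-32 core CGATA in 23.3% and 12.1% (odds ratio 2.20, adjusted exact p = 4.29e-117). GAGAGAG and CACACACA were lower at summits, with odds ratios of 0.501 and 0.447, and the call for GAGAGAG was lost in windows of 100 bp to either side (odds ratio 0.870, Fisher's exact test, adjusted p = 0.0562). Of 18 fixed motifs 10 were higher and 4 lower by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment. Against windows of the same width at the TSSs of unbound genes, an unlike comparison since about 50% of summits lie outside promoters, the odds ratio was 1.46 for the DRE (adjusted exact p = 3.69e-06) and 0.994 for Motif 1 (adjusted exact p = 0.964). Between the most upstream TSSs of bound and unbound genes, a comparison added after the data were seen, the odds ratios were 3.45 and 3.35.

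Among 32896 8-mers tested in odd-ranked peaks, 715 were higher at summits (adjusted p below 0.05, one-sided Fisher's exact test with Benjamini-Hochberg adjustment). The first was TATCGATA, followed by ATCGATAG and ATCGATAA, which overlap it, and GGTCACAC, part of Motif 1. All 10 of the top 8-mers were also higher in even-ranked peaks, where TATCGATA was in 4.64% of windows and 0.480% of flanks. None of the 15 strongest peaks held TATCGATA, but at its share of 4.61% over all reproducible peaks so few peaks can hold none by chance.

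**Figure D3:**
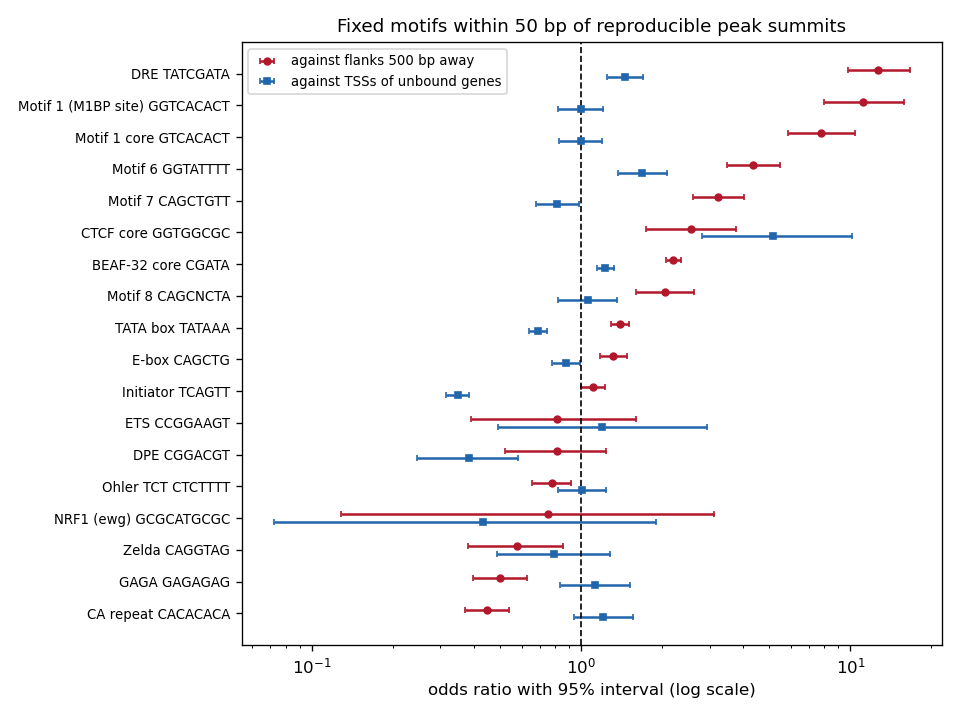
Odds ratios with 95% intervals (horizontal axis, log scale) of 18 fixed motifs within 50 bp of reproducible summits, against flanks 500 bp away (red circles) and against TSSs of unbound genes (blue squares). The DRE lies at 12.7 and 1.46, and Motif 1 at 11.1 and 0.994.

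The tagged gene lies on chromosome 2R at positions 7513846 to 7516390, on the minus strand. Its locus was examined since a transgene can add copies of it, and any effect of copy number on peaks there was not tested. The promoter of the gene carried a reproducible peak of rank 6157 (signal 223.3, positions 7516206 to 7516535), with rank 6227 in replicate 2 and 6644 in replicate 3. The gene and 20 kb on either side held 11 reproducible peaks, compared with a median of 4 in 2000 windows of the same length at randomly drawn genes, of which 3.40% held as many. In the lists of 30000 peaks the same window held 16 (pooled), 17 (replicate 2) and 17 (replicate 3) peaks, numbers reached by 24.4%, 19.8% and 23.4% of the random windows. The strongest of the 11 reproducible peaks, at positions 7533195 to 7533510, had rank 533.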

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

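Peaks of the pooled list that fell below the reproducible list were used in no motif, promoter or gene comparison above and were examined for the DRE after its share at reproducible peaks had been seen. Of 21037 such peaks, 137 held TATCGATA within 50 bp of the summit (0.651%), against 0.359% of their flank windows (odds ratio 1.82, 95% interval 1.43 to 2.31, two-sided Fisher's exact test). They stood out because the sequence was counted in peaks outside the reproducible list, with no control samples to set the count against, so that the flanks served instead. At TSSs lay 19.0% of these summits.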

How the results depend on the processing

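Promoter share, replicate overlap, the strong against weak comparison, the mitochondrial gene union and divergent promoters kept their direction and side of the threshold under each alternative run, and X against autosomes gave no call (odds ratio 0.960 to 1.09); the mitochondrial odds ratio ranged from 2.11 to 4.38, the latter without sibling copies, an alternative added after the data were seen. The strongest 8963 pooled peaks are the reproducible list itself, so that alternative tests nothing. The 4481 strongest peaks gave 3211 bound genes by its construction. Restricting the background to genes with a summit in a replicate's full list, also added later, left 8 gene lists past the threshold in place of 15 (4 higher and 4 lower): mitochondrial ribosomal proteins, complexes II and III, mtDNA maintenance, glycolytic, Dom/Tip60, insulator and neuronal genes dropped out, histones kept no member, and proteasome and muscle genes entered; the cause was not tested. Against TSSs of unbound genes 7 fixed motifs passed in place of 14, and 1123 8-mers in place of 715. The first 8-mer was then AATATTTG, and neither TATCGATA nor GGTCACAC was among the top 10. The odds ratio crossed 1 for Motif 1 (0.994) and its core (0.995), Motif 7 (0.815), the E-box (0.879), the TATA box (0.693), the Initiator (0.348), GAGAGAG (1.12), CTCTTTT (1.01) and CACACACA (1.20), and the cause was not tested. Between the most upstream TSSs of bound and unbound genes (100 bp to either side) the odds ratio was 3.35 for Motif 1, 3.20 for its core, 2.63 for Motif 7 and 1.93 for the E-box. There it stayed below 1 for the TATA box (0.652) and the Initiator (0.537), and the intervals of GAGAGAG, CTCTTTT and CACACACA held 1. Of single list calls, 13 were lost and 3 gained under the choices made in advance, the lost ones including complex III, mtDNA maintenance and glycolytic genes at 1000 bp (adjusted p = 0.0617 for each, Fisher's exact test with Benjamini-Hochberg adjustment), and of named genes 67 calls were lost and 10 gained. Read depth, the control and sites beyond the cap of 30000 peaks limit all of these results.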

Other observations

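The values in this part were chosen after the data were seen, except the comparison of mitochondrial genes without another TSS within 1 kb, and of the 14 tests 9 were chosen only after the result, or values that largely fix it, had been seen. That mitochondrial comparison was planned, and was put to use as a test after its value was seen. The other 4 are those on repeats (at single-replicate peaks and at the 428 peaks of any rank in repeat-rich regions), on motifs at promoter peaks of replicate 3 alone and on the DRE at mitochondrial promoters. The 14 tests carry no adjustment. Windows of 100 bp to either side of each gene's most upstream TSS, which need not be the TSS near the peak, were compared between bound and unbound genes. Of 18 motifs, 9 were higher and 3 lower by Fisher's exact test with Benjamini-Hochberg adjustment, the nested motifs counted separately. The DRE was in the windows of 14.0% of 4919 bound and 4.50% of 9026 unbound genes (odds ratio 3.45, 95% interval 3.03 to 3.93). Motif 1 was in 9.45% and 3.02% (odds ratio 3.35), and Motif 7 in 9.84% and 3.99% (odds ratio 2.63). The Initiator (odds ratio 0.537) and the TATA box (odds ratio 0.652) were lower in the windows of bound genes. On chromosome 4, 56 of 80 genes were bound (70%, odds ratio 4.36 against 2L, 2R, 3L and 3R, 95% interval 2.65 to 7.36).

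Sibling copies of mitochondrial subunit genes, those named as likes of another gene and the Tim17 copies Tim17a1, Tim17a2, Tim17b1 and Tim17b2, were bound in 1 of 25 cases (COX7AL), against 140 of 200 other members (odds ratio 0.0181). Thus ND-20L, COX4L, UQCR-11L and ATPsynCF6L were unbound. The DRE did not distinguish bound mitochondrial promoters: it was in 9.93% of their strongest peaks and 10.1% of those of other bound genes (odds ratio 0.985, 95% interval 0.519 to 1.73).

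TCAAGATA (TATCTTGA on the other strand) was in 6 of the 25 strongest peaks, and among ranks 26 to 250, where its counts were seen before the test was set, in 13 of 225 peaks and 0 of 450 flank windows (lower 95% bound of the odds ratio 6.37). Its odds ratio against flanks was 8.05 (95% interval 0.793 to 397) among the next 500 peaks after the strongest 500. It was 1.25 (0.507 to 2.94) among the 2000 after those, and 2.12 (1.05 to 4.29) at ranks 6001 to 8963. TATCGATA was in 3.20% of the strongest 500 peaks, 5% of the next 500, 6.80% of the next 2000 and 2.97% at ranks 6001 to 8963. The strongest 500 against those 2000, the set with the highest share, gave an odds ratio of 0.453 (95% interval 0.250 to 0.772), and low shares were thus not particular to the strongest peaks.

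Mitochondrial genes were bound more often than other genes. If a neighbour's peak counted for both genes were the whole cause, the odds ratio would be about 1 among genes with no other TSS within 1 kb. There it was 2.94 (95% interval 1.82 to 4.73), for 77 of the 225 mitochondrial genes. A partial role stays open. With each peak given to the gene of the nearest TSS only, the odds ratio was 2.11, as given above. Mitochondrial ribosomal protein genes then fell from 49 to 25 bound of 75. A general preference for promoters of broadly used genes may account for the pattern and cannot be told apart from it, since the answer turned on which genes stood for that class. Against ribosomal protein, proteasome and cytosolic synthetase genes together, a comparison whose bound was set after their shares were seen, the odds ratio was 0.603 (95% interval 0.376 to 0.960). Without the ribosomal protein genes it was 1.58 (95% interval 0.873 to 2.85). The design has no second condition, so no biological explanation was tested.

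Peaks in 1 replicate alone among its strongest 8963 numbered 273 in replicate 2 and 498 in replicate 3, with median ranks of 6259 and 5760. They lay at promoters in 40.7% and 70.7% of cases, against 45.8% and 47.4% of next-ranked shared peaks. The median fall in signal needed to leave the other list was 5.64 SD of the log2 ratio at shared peaks, but taking the strongest 8963 peaks alone fixes it above 3.78 SD, so this decides nothing. A further peak of the other replicate lay within 1000 bp of 226 of 771 such peaks, against 478 of 771 next-ranked shared peaks (odds ratio 0.254). The former were chosen for lacking an overlapping peak and the latter for having one. This ratio thus cannot decide whether a neighbouring peak stood in its place. Repeats did not go with these single-replicate peaks (odds ratio 0.727, 95% interval 0.411 to 1.27). Promoter peaks of replicate 3 alone held TATCGATA or GGTCACACT more often than shared ones (odds ratio 2.04, 95% interval 1.26 to 3.40), against a lack of these motifs. A fall past the end of the other list, a neighbouring peak and an unstated step of the peak calling or filtering all stay open as possible causes. No biological explanation was tested for these peaks.

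The strongest 250 peaks lay on chromosome 4 or in repeat-rich bins in 22.4% of cases, against 4.27% of the rest (odds ratio 6.47, 95% interval 4.63 to 8.93). Mostly masked windows were at 1 of these 56 peaks, against 32.6% of random positions in the peaks' own bins (odds ratio 0.0377, 95% interval 0.000936 to 0.219). They were at 10.3% of all 428 reproducible peaks in such bins (odds ratio 0.197 against random positions there). Most of these summits thus lay outside masked repeats. The random positions were not matched for promoters, and the handling of reads with several matches is unknown. Whether reads of repeats raised the signal there thus cannot be decided. Background spread evenly over a region and called as peaks is argued against by promoters at 50 of the 56, against 4.98% of positions in their own bins (odds ratio 158, 95% interval 67.1 to 456), and at 41.4% of the 428 (odds ratio 19.8). The comparison cannot judge background that is itself higher at promoters, since no control was analysed. A control that is low in repeat-rich regions, which could raise their signal, was not tested, and no biological explanation was tested.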
